A study of Homo sapiens with 23 samples.

How the data were processed

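RNA of 23 libraries was sequenced from 3 human cell lines, 20 libraries from xenografts and 3 from culture. The sources used here name it poly-A RNA. Mitochondrial rRNA, however, took 35.3% to 42.0% of the counts in the IM9 xenograft libraries, against 0.900% in the IM9 culture. Whether all libraries were selected for poly-A RNA in the same way was not tested. Per the labels, the cells carried luciferase, fluorescent proteins or Cas9 and were sorted by fluorescence after recovery. Chip tumours were minced, digested and mixed with the flush of the chip, and marrow was flushed. Libraries were made with the Illumina TruSeq kit and read as pairs, per the labels' protocols. Whether strand was used in counting is not given in the sources used here, so antisense and overlapping genes could not be told apart.

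The authors deposited 1 table per library with 196501 transcripts, each with a length, an effective length, an estimated count and a transcripts-per-million (TPM) value, per the file headers, which have the form that kallisto writes. The submitters' processing notes name kallisto, TopHat2, DESeq2 and the build GRCh37, with no versions, order or roles. Which of these tools made the deposited estimated counts, and the release of the transcript annotation, are not given in the sources used here. Such estimates divide reads among transcripts of similar sequence, so close paralogues and pseudogenes carry added uncertainty.

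Transcripts were matched by identifier to GENCODE v29 on GRCh38, which gave gene names and positions. It matched 181854 transcripts, 93.2% of them with identical length, to 52989 genes, 19426 of them protein-coding, and 14647 did not match. A pair of unmatched transcripts with the lengths of ribosomal RNAs took large shares in some libraries, and the remaining unmatched transcripts 1.57% to 4.39% of the counts. Unmatched transcripts were left out of library sizes and tests. Estimated counts were summed per gene and rounded to whole numbers. The 476 genes on chromosome Y or XIST were not reported.

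The unit of comparison was 1 mouse and site, with left and right IM9 libraries of a mouse summed, which gave 8 marrow and 8 chip units from 8 mice. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalisation, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). The SE given with a log2 fold change was computed back from the test. It is the absolute fold change before shrinkage divided by the square root of the F statistic. Site across lines was fitted with line as a covariate. Site within a line, and the difference of the site effect between lines, came from 1 fit over the 6 groups of line and site, which share an estimate of spread. Xenograft against culture set 3 culture libraries against 3 sums of all xenograft libraries of a line, with line as a block. The tests covered 27069 genes with all units, 27102 without the OPM2 marrow unit of mouse M361 and 22016 for culture. A count of 1 culture per line means that the spread there is one between lines. It is estimated in part across genes, the more so without IM9.

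Gene lists were tested with camera and fry in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with an estimated correlation. There were 37 lists, 28 of cell programmes and 9 of other cell types, with 975 symbols of which 958 matched. Some genes stand in more than 1 list: p53 targets and apoptosis regulators share BAX, BBC3, TNFRSF10B and FAS, p53 targets and immediate early genes BTG2, and immediate early genes and apoptosis regulators MCL1. The lists, the designs, the alternatives and the rule for genes to name were fixed before the data were examined. The rule took, of genes past the threshold with a mean log2 CPM of at least 2, the 12 higher and 12 lower with the largest change across lines and the same sign in all 3 lines. Within a line it took 8 and 8 whose marrow and chip units did not overlap. For each list described it took up to 4 members with the smallest p, and always a set of myeloma genes such as HMGA1, PA2G4, MYC, CXCR4 and IRF4. Immunoglobulin and HLA genes were left out by the rule. It was applied again without the marrow unit of mouse M361 and, for culture, without IM9, after these values were seen.

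The mouse numbers in the titles were read as marking the same animal at both sites, so that they pair the samples. Within a mouse, the correlation of the marrow and chip deviations from their group means was 0.055, 0.073 and −0.023 in MM.1S. It was 0.066, −0.022 and 0.174 in OPM2 and 0.213 in both IM9 mice. The IM9 values are the same by construction. Each IM9 group held only the units of these mice, whose deviations from the group mean are equal and opposite. The IM9 mice therefore do not check the pairing independently of each other. The fit without the mouse was the one planned, and the blocked value is given where it changes a call. Replicates were compared before averaging: no pair of units agreed within counting noise (chi-square per degree of freedom at least 16.9), so each was counted once.

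Depth ranged from 9591241 to 72242136 estimated counts per library. Shares of counts have Wilson 95% intervals. The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds, 50 per fold size. Across lines with all units, 62% of 4-fold and 98% of 8-fold changes were recovered, and 100% of both without the unit of mouse M361. Within MM.1S, OPM2 and IM9 with all units, 34%, 22% and 8% of 8-fold changes were recovered, and 88%, 92% and 94% without that unit. For culture 76% of 8-fold changes were recovered. False calls numbered 0 to 11 per comparison. The simulation gave all units the same spread for a gene, with no unit noisier than another and no effect of the mouse. The data differ from this, above all in OPM2 marrow, so these recovery rates and false calls may not hold for the real fits.

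The alternatives fixed with the lists were DESeq2 size factors, the DESeq2 1.42.0 test, limma-voom, no filter, counts from length-scaled TPM, the mouse as a block, IM9 sides kept apart, each line fitted alone, each unit or line left out, and other sums for culture. Chosen after seeing the data were the use of the fit without mouse M361's marrow unit for lists and named genes, fits on nuclear protein-coding genes only, fits without OPM2, IM9 alone with sides apart, OPM2 alone without that unit, combinations of these with the block, and culture fits of MM.1S and OPM2 by site. Tables were built with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. A mouse genome was not used here, so reads of host origin were not separated.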

Results

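The series follows human myeloma cells that grew in a bone chip implanted into immunodeficient mice and then spread to the bone marrow of the same animals. RNA was sequenced from 3 cell lines. MM.1S (MM1S in the plots) and OPM2 are lines derived from multiple myeloma, a cancer of plasma cells, and IM9 is a B-lymphoblastoid line. Cells of each line were recovered from the chip, where the tumour was started, and from femur or tibia marrow, where it had spread. Each line also had 1 library from cells in culture. The 23 libraries fall into 9 groups. MM.1S and OPM2 had 3 marrow and 3 chip libraries each, from 3 mice per line. IM9 had 4 marrow and 4 chip libraries from left and right sides of 2 mice, and the sides were summed, so that the 16 units compared were 8 marrow and 8 chip samples from 8 mice.

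Depth ranged from 9591241 to 72242136 estimated counts per library and differed by site. OPM2 marrow libraries held 14656376 to 25263443 counts and OPM2 chip libraries 46567514 to 66457152. IM9 marrow libraries held 9591241 to 18990305 and IM9 chip libraries 14685118 to 35198761. In MM.1S the sites were closer, with 41940506 to 47130943 in marrow and 35521994 to 72242136 in chip. The cultures of MM.1S, OPM2 and IM9 held 43838690, 40077192 and 60426365. Mitochondrial rRNA took 35.3% to 42.0% of the counts in the IM9 xenograft libraries and 0.900% in the IM9 culture. Protein-coding transcripts held 22.7% to 38.3% of the counts in the IM9 xenograft libraries, against 82.6% in the culture. The 95% Wilson interval of any such share was at most 0.0309 percentage points to either side, which covers counting error only.

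The OPM2 marrow library of mouse M361 stood apart. It had 21841 transcripts above 0 and 6615 coding genes with a counts-per-million (CPM) value of 1 or more, and MALAT1, a nuclear non-coding RNA, took 31.1% of its counts. Its correlation with the OPM2 marrow libraries of mice M364 and M368 was 0.471 and 0.516 on the log2 CPM scale, across genes. Mitochondrial mRNA made up 16.3% of its counts, 37.4% in mouse M364 and 15.2% in mouse M368, against 1.86% to 3.83% in the OPM2 chip libraries. MM.1S marrow libraries held 5.54% to 12.6% mitochondrial mRNA and MM.1S chip libraries 3.34% to 4.40%. Because the library of mouse M361 widened the spread estimated for all genes, the count of genes in each comparison of sites is given with and without it, and lists and named genes mainly without it, a choice made after its values were seen.

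**Figure D1:**
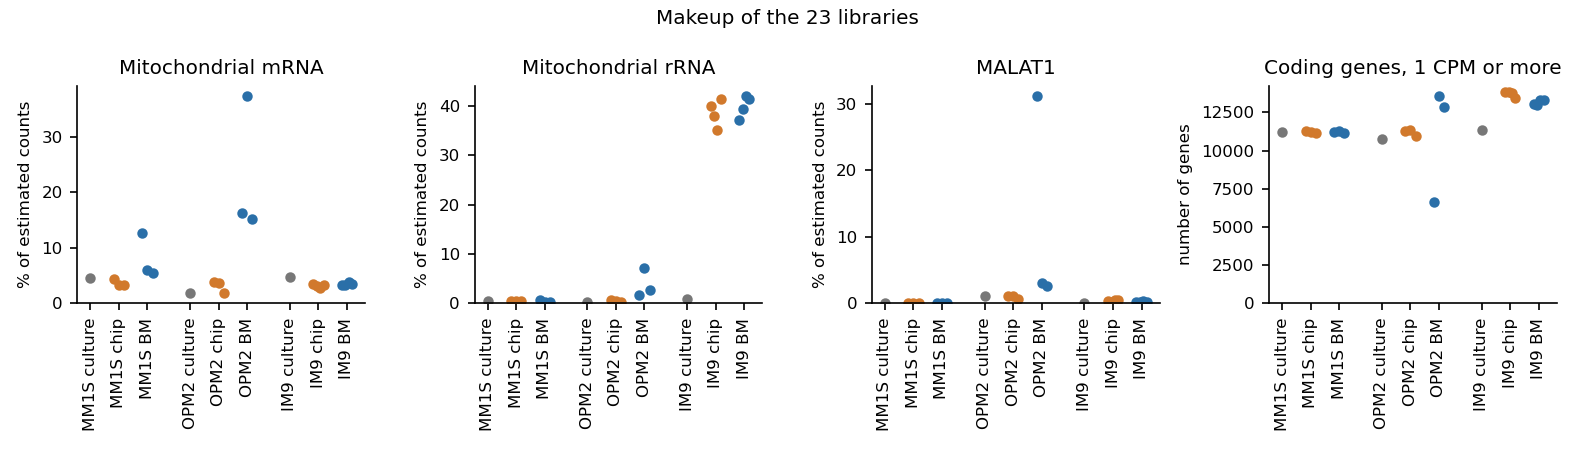
Share of estimated counts on mitochondrial mRNA, mitochondrial rRNA and MALAT1 (percent), and number of coding genes at 1 CPM or more, for each of the 23 libraries by group (grey, culture; orange, chip; blue, marrow). The OPM2 marrow library of mouse M361 stands out with 31.1% MALAT1 and 6615 coding genes, and the IM9 xenograft libraries with 35.3% to 42.0% mitochondrial rRNA.

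Which transcripts differ between cells at the implantation site and cells that reached the marrow was asked first across the lines. Immediate early genes, a group switched on within minutes of stimulation or handling, were lower in marrow. FOS, a subunit of the AP-1 transcription factor, had a log2 fold change of −6.51 ± 0.73 (SE, here and for other log2 fold changes; 8 marrow and 8 chip units) with an edgeR adjusted p of 0.000723, and was lower in 8 of 8 mice. In MM.1S it went from 515 ± 97.7 CPM in chip to 4.07 ± 1.5 CPM in marrow (SD, n = 3 each), in OPM2 from 565 ± 396 to 5.74 ± 8.03 (SD, n = 3 each) and in IM9 from 35.6 ± 22.4 to 0.754 ± 0.649 (SD, n = 2 each). EGR1, a zinc-finger factor induced by growth signals, had −4.97 ± 0.54 (adjusted p = 0.000723), and the stress factor ATF3 −4.06 ± 0.52 (adjusted p = 0.00334), each lower in 8 of 8 mice. CDKN1A, which encodes the cell cycle inhibitor p21, had −3.16 ± 0.57 (adjusted p = 0.0429).

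Of 27069 genes tested with all units, 19 passed, 16 lower and 3 higher in marrow, and 3638 had an unadjusted p under 0.05. Beside FOS, EGR1, ATF3 and CDKN1A, the naming rule took FOSB at −5.47 ± 0.88, DUSP1 at −4.89 ± 0.89, NR4A2 at −4.83 ± 0.73, PPP1R15A at −4.20 ± 0.59, JUNB at −3.21 ± 0.55, SOCS3 at −3.11 ± 0.55 and MAFF at −1.97 ± 0.29. These encode AP-1 and related transcription factors, a nuclear receptor, a MAP kinase phosphatase, a regulator of protein synthesis under stress and an inhibitor of cytokine signalling. The 3 genes that were higher lay outside the rule and were chosen after their values were seen: MMP8, a neutrophil collagenase, at 6.07 ± 1.14, and AC068724.1 and CYCSP48 at 4.94 ± 1.11 and 4.79 ± 1.13, all at very low levels. The balance of directions turned by DESeq2, with 555 higher and 358 lower, and with no filter on low counts, with 388 higher and 114 lower. With the mouse as a block 4 genes passed, all lower. Of the 11 genes named, FOS, EGR1 and ATF3 then kept the call, and adjusted p ranged from 0.00158 to 0.496. Without the marrow library of mouse M361, 517 of 27102 genes passed, 149 of them higher and the others lower, and these included all 19. With the block as well, 88 passed, 82 lower and 6 higher, of which 87 were among the 517.

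The immediate early list was fixed beforehand under the name dissociation and immediate early response, so by its name it also stands for tissue dissociation. Of its 31 tested members, 10 fell with all units and 21 did not pass, with 23 lower when adjusted over the list alone. The list's median log2 fold change was −2.42 (camera adjusted p = 1.63e-25), and it was lower with an estimated correlation too (adjusted p = 0.013). Without the library of mouse M361, 23 of the 31 fell, 26 when adjusted over the list alone, with a median of −2.21 and an adjusted p of 0.00199 with an estimated correlation. JUN, the AP-1 partner of FOS, then passed at −4.49 ± 0.31 (adjusted p = 6.19e-07) and NR4A1, an orphan nuclear receptor, at −5.65 ± 0.66 (adjusted p = 0.000183), each lower in 7 of 7 mice. The chip tumours had been minced and digested with collagenase and Dispase, whereas the marrow was only flushed. Handling and site therefore cannot be told apart for any gene or list compared between marrow and chip.

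Targets of the tumour suppressor p53 were also lower in marrow, where handling is tied to site as well. Without the marrow library of mouse M361, the list's median difference from culture in chip was 0.75, −0.45 and −0.92 for MM.1S, OPM2 and IM9. In marrow it was −0.2, −1.58 and −1.26, so the chip cells lay above culture in MM.1S alone. Without the library of mouse M361, 11 of 27 fell, 22 when adjusted over the list alone, and the median was −0.91 (adjusted p = 6.9e-17, and 0.000851 with an estimated correlation). CDKN1A had −2.87 ± 0.37 (adjusted p = 0.000496). SESN1, a stress-induced brake on growth signalling, had −1.35 ± 0.18, the death receptor gene TNFRSF10B −1.32 ± 0.19, and BBC3, which encodes the pro-apoptotic protein PUMA, −1.55 ± 0.22, each lower in 7 of 7 mice. With all units 1 of the 27 fell, 7 when adjusted over the list alone, and the call was lost (adjusted p = 0.306 with an estimated correlation). Of 28 apoptosis regulators 4 fell without that library, 10 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00199 with an estimated correlation). They included TNFRSF10B and BBC3, which are in both lists, and MCL1, an inhibitor of apoptosis and also an immediate early list member, at −1.24 ± 0.18 (adjusted p = 0.00127). BIRC2, another inhibitor of apoptosis, had −0.63 ± 0.15 (adjusted p = 0.0355, and 0.167 with the block). With all units none of the 28 passed, 3 did when adjusted over the list alone, and the adjusted p was 0.479 with an estimated correlation.

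**Figure D2:**
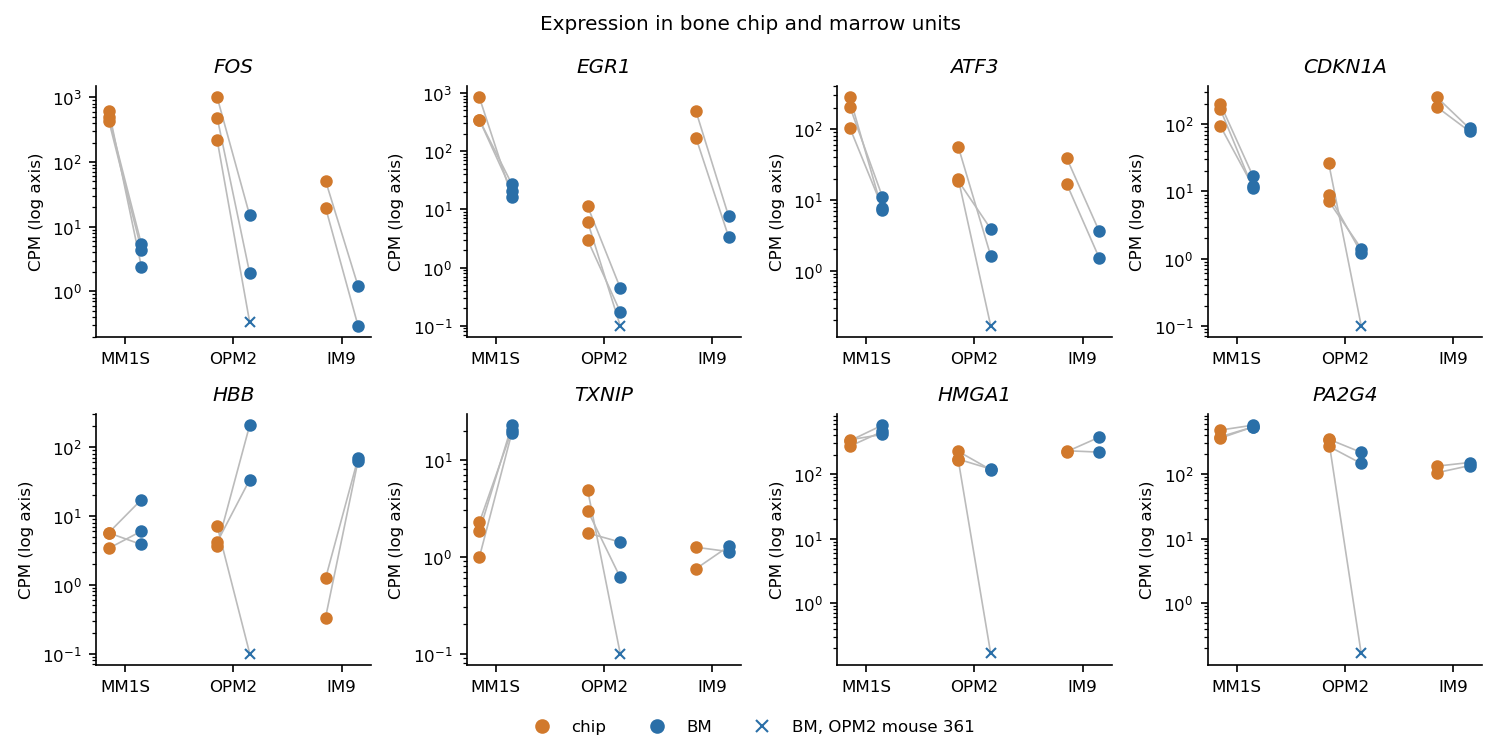
CPM (log axis) of FOS, EGR1, ATF3, CDKN1A, HBB, TXNIP, HMGA1 and PA2G4 in chip and marrow units, with a line joining the units of each mouse and the OPM2 marrow unit of mouse M361 drawn as a cross. Values under 0.1 CPM are drawn at 0.1, FOS, EGR1, ATF3 and CDKN1A are lower in marrow in 8 of 8 mice, and HMGA1 and PA2G4 show no shared direction.

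Other groups were lower across the lines without the library of mouse M361, unevenly by line, and for these the list calls were lost with an estimated correlation. Of 16 heat shock genes 3 fell, 6 when adjusted over the list alone (median −0.62, adjusted p = 0.27 with an estimated correlation), and the medians in MM.1S, OPM2 and IM9 were 0.07, −0.83 and −0.59. The chaperone genes HSPA1B, whose reads are shared with its near-identical neighbour HSPA1A, DNAJB1 and BAG3 had −4.44 ± 0.35, −2.88 ± 0.36 and −1.64 ± 0.26. Of 35 glycolysis and hypoxia genes 8 fell, 12 lower and 1 higher when adjusted over the list alone (median −0.44, adjusted p = 0.128 with an estimated correlation), with medians in the same order of −0.20, −1.34 and −0.09. DDIT4, an inhibitor of mTORC1, had −1.60 ± 0.24 and PFKFB3, an activator of glycolysis, −1.11 ± 0.18. VEGFA, the angiogenic growth factor, had −1.22 ± 0.24 (adjusted p = 0.0126, and 0.0818 with the block) and was lower in 7 of 7 mice. Of 29 lysosome and autophagy genes 4 fell, 10 lower and 1 higher when adjusted over the list alone (median −0.49, adjusted p = 0.274 with an estimated correlation), with medians in that order of −0.20, −1.36 and 0.04. The autophagosome gene MAP1LC3B had −1.06 ± 0.20 (adjusted p = 0.0107, and 0.106 with the block). With all units no member of these 3 lists passed in edgeR, also when adjusted over the list alone, and the medians were −0.29, −0.68 and −0.74 (adjusted p = 0.407, 0.554 and 0.554 with an estimated correlation), with 0.20 for heat shock in OPM2.

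Mitochondrial transcripts were higher in marrow across the lines without that library. Of 13 tested genes of the mitochondrial genome 7 rose, and 13 when adjusted over the list alone (median 1.68, adjusted p = 0.291 with an estimated correlation). The median was 1.27 in MM.1S, 3.38 in OPM2 and 0.26 in IM9, where the shares of mitochondrial mRNA overlapped, with 3.20% to 3.77% in marrow and 2.73% to 3.52% in chip libraries. With all units 0 of the 13 passed in edgeR, 13 when adjusted over the list alone (median 1.72, adjusted p = 0.306 with an estimated correlation). MT-CO3, a subunit of cytochrome c oxidase, had 2.03 ± 0.39 and MT-ND1, a subunit of complex I, 2.09 ± 0.42, each higher in 7 of 7 mice (adjusted p = 0.011 and 0.0135). Nuclear copies of these genes share sequence with them, which leaves the division of reads uncertain. Beside them the naming rule took HBB, the beta-globin gene, at 3.71 ± 0.80 (adjusted p = 0.0224, higher in 6 of 7 mice) and MIR17HG, the host gene of the miR-17 cluster, at 1.49 ± 0.26 (adjusted p = 0.00562, higher in 6 of 7 mice). None of the 12 genes named as higher kept the call with the mouse as a block (adjusted p from 0.0822 to 0.361), whereas 11 of the 12 named as lower did.

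**Figure D3:**
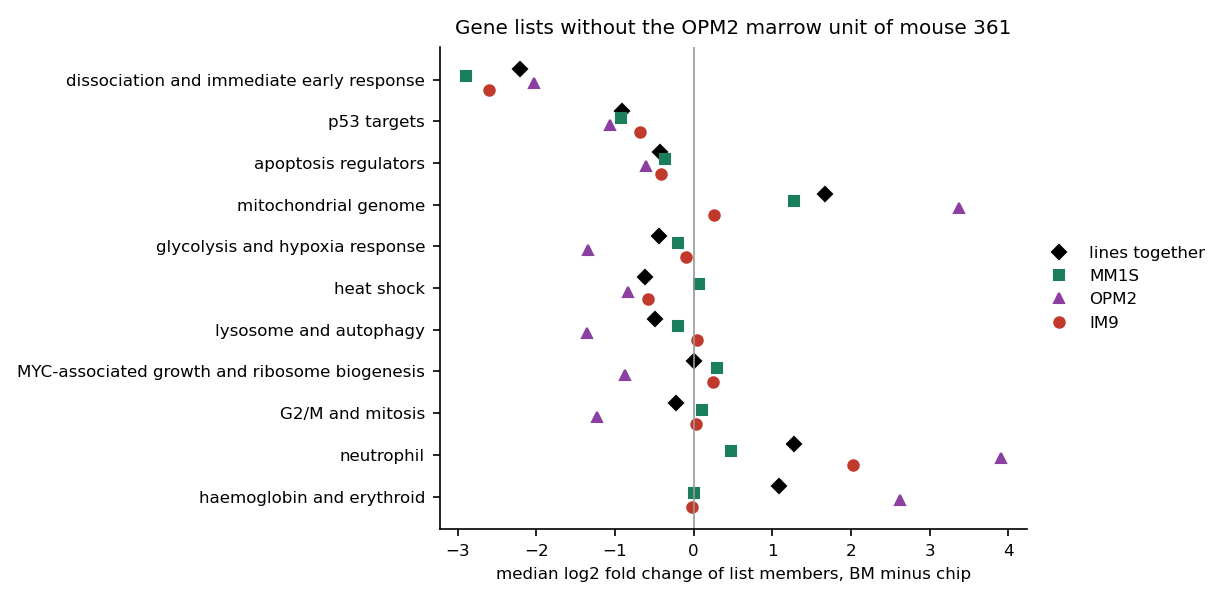
Median log2 fold change, marrow minus chip, of 11 gene lists without the OPM2 marrow library of mouse M361, for the lines together (diamonds), MM.1S (squares), OPM2 (triangles) and IM9 (circles). The immediate early list lies at −2.21 for the lines together and below 0 in each line, and the mitochondrial genome list reaches 3.38 in OPM2.

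In MM.1S, marrow cells had less of the AP-1 and NR4A factors than chip cells and, without the library of mouse M361, more of the plasma cell regulator IRF4. With all units 11 of 27069 genes passed, 8 lower and 3 higher (968 at an unadjusted p under 0.05), and with counts from length-scaled TPM 7 lower and 0 higher. FOSB fell by 7.99 on the log2 scale (adjusted p = 0.00456), NR4A2 and NR4A1 passed at adjusted p of 0.00456 and 0.023, and none of these kept the call with the mouse as a block (adjusted p from 0.098 to 0.422), where 0 genes passed in edgeR with 753 at an unadjusted p under 0.05. Fitted on MM.1S units alone, with no unit left out, 2777 of 15299 genes passed in edgeR, 1132 higher and 1645 lower. In the joint fit without the library of mouse M361, which enters through the shared estimate of spread, 406 passed, 281 lower and 125 higher. These included all 11, and with the block 858 passed, 398 of them shared. FOSB then had −8.02 ± 0.70 (adjusted p = 1.23e-05) and NR4A1 −7.72 ± 0.66 (adjusted p = 1e-05). The 3 genes higher with all units lay outside the naming rule and were chosen after their values were seen: IL2RB, an interleukin-2 receptor subunit gene, at 3.69 ± 0.55, GTF2IRD2B, which has a near-identical copy, at 3.66 ± 0.55, and AC026495.1 at 5.26 ± 0.88. Of the genes the rule took without mouse M361's marrow, CTAG2, a cancer-testis antigen gene with close paralogues, rose from 3.96 ± 1.01 to 60.3 ± 32.1 CPM (log2 fold change 3.92 ± 0.47, adjusted p = 0.00032), and TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose from 1.69 ± 0.643 to 20.6 ± 1.89 CPM (3.59 ± 0.43, adjusted p = 0.000298; SD, n = 3 each). The DNA methyltransferase gene DNMT3B rose by 2.42 ± 0.30 and HES1, a Notch target, by 2.20 ± 0.49.

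Again without that library, IRF4, on which myeloma cells depend, rose in MM.1S from 289 ± 16.6 to 765 ± 113 CPM (1.37 ± 0.24, adjusted p = 0.00756), and CD38, a plasma cell surface protein, by 1.12 ± 0.24 (adjusted p = 0.0274). MAF, the transcription factor activated by translocation in this line, fell from 574 ± 96.2 to 241 ± 16.9 CPM (−1.27 ± 0.24, adjusted p = 0.0113). Of 31 immediate early genes 20 fell, 24 when adjusted over the list alone (median −2.89, adjusted p = 0.0187 with an estimated correlation, and 0.0885 with the block as well). Of 27 p53 targets 11 fell, 19 when adjusted over the list alone (median −0.92, adjusted p = 0.000332 with an estimated correlation). CDKN1A went from 154 ± 54.2 to 13.4 ± 3.16 CPM, and PHLDA3, an inhibitor of AKT, had −3.06 ± 0.36. The transferrin receptor gene TFRC fell from 1079 ± 129 to 153 ± 58.7 CPM (−2.84 ± 0.24), and MT-CO3 had 1.84 ± 0.34 beside the higher mitochondrial share of these libraries. With all units none of these 7 genes passed in edgeR (adjusted p from 0.171 to 1), 5 immediate early genes and 0 p53 targets fell (20 and 3 when adjusted over the list alone), and the adjusted p with an estimated correlation was 0.00581 and 0.283. Of 53 MYC-associated growth and ribosome biogenesis genes 48 had a positive log2 fold change and 0 passed in edgeR (median 0.30, adjusted p = 0.296 with an estimated correlation).

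In OPM2 the difference between sites was broad. The median log2 fold changes of the lists for ribosome biogenesis, mitosis and glycolysis were below 0 without the library of mouse M361, and that of mitochondrial transcripts was above 0. None of these list calls held with an estimated correlation (adjusted p = 0.154, 0.177, 0.116 and 0.3). GAPDH, a glycolytic enzyme gene, had a mean of 3113 ± 530 CPM in chip (SD, n = 3) and 572 CPM in the other 2 marrow units (log2 fold change −2.29 ± 0.22, adjusted p = 6.38e-06). NUSAP1, a spindle protein gene, had −1.93 ± 0.23 and GRWD1, a ribosome assembly factor gene, −1.64 ± 0.19. PCSK5, which encodes a proprotein convertase, rose from 45.8 ± 22.4 to 1496 CPM (5.19 ± 0.43, adjusted p = 3.34e-06).

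With all units 7738 of 27069 genes passed in OPM2, 5820 higher and 1918 lower, and these calls rest on the spread shared with the other lines. Fitted on OPM2 units alone, 0 genes passed in edgeR with all units (4263 at an unadjusted p under 0.05), and 9832 without the library of mouse M361. Without the library of mouse M361 there were 13175, 8304 higher and 4871 lower, of which 7146 were shared. Higher calls were more frequent outside nuclear coding genes than among them: of 15879 nuclear coding genes 3696 rose and 4618 fell (median −0.146), and of 11223 other genes 4608 rose and 253 fell (median 1.59). Normalised on nuclear coding genes alone without that library, 4287 rose and 3718 fell, and the median of all these genes moved by 0.216. The block gave 3534 with all units. Several of the largest rises with all units rested on mouse M361, in whose marrow RHD, a blood group gene with a close paralogue, reached 2460 CPM, MDM2 5825 CPM and JUN 5840 CPM. Without it MDM2 had 1.61 ± 0.32, and JUN fell (−4.57 ± 0.46). NUSAP1, KIF20A, HSPA1B and DNAJB1 likewise were above 0 with all units and below 0 without it. With the block 2 of the 8 genes named as higher with all units kept the call (adjusted p from 0.022 to 0.27).

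By lists in OPM2 without that library, 32 of 53 MYC-associated growth genes fell and 21 did not pass (33 lower when adjusted over the list alone, median −0.87), among them IPO4, LAS1L and MYBBP1A at −2.03 ± 0.24, −1.97 ± 0.24 and −2.25 ± 0.28. Of 30 G2/M genes 22 fell and 1 rose (23 and 1 when adjusted over the list alone, median −1.23), among them KIF20A, a mitotic kinesin, at −2.06 ± 0.28. Of 35 glycolysis and hypoxia genes 23 fell and 4 rose (median −1.34), with PFKL at −2.53 ± 0.28 and PKM at −2.11 ± 0.24. Of 31 immediate early genes 19 fell and 4 rose (20 and 4 when adjusted over the list alone, median −2.03), and of 27 p53 targets 14 fell and 2 rose (15 and 2, median −1.07). All 13 mitochondrial genes rose (median 3.38), in libraries whose mitochondrial mRNA share is given above. With an estimated correlation the calls of immediate early genes (adjusted p = 0.211) and p53 targets (adjusted p = 0.0529) were lost as well. With all units 6 MYC-associated genes fell and 1 rose (2 and 0 when adjusted over the list alone), 7 and 4 of the G2/M list (10 and 4) and 11 and 5 of glycolysis and hypoxia (14 and 6). Normalised on nuclear coding genes alone without that library the medians were −0.65 for MYC-associated genes, −1.01 for G2/M and −1.13 for glycolysis and hypoxia.

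Of 34 adhesion and marrow homing genes in OPM2 13 fell and 5 rose without that library, also when adjusted over the list alone, and of 21 plasma cell identity genes 9 and 1 (adjusted p = 0.177 and 0.201 with an estimated correlation). ITGB1 and ITGA4, the subunits of the fibronectin and VCAM1 receptor, had −2.38 ± 0.42 and −1.88 ± 0.30. The hyaluronan receptor gene CD44 and the syndecan gene SDC1 each had −1.77, with standard errors of 0.28 and 0.35 (adjusted p = 0.000122 and 0.000785). IRF4 had −1.14 ± 0.28 and CCND3 −1.21 ± 0.24. NSD2 and FGFR3, the genes activated by translocation in this line, had −0.48 ± 0.18 (adjusted p = 0.0352, and 0.0594 with the block) and 813 ± 108 CPM in chip with no call between sites. CXCR4 had 0.74 ± 0.31 (adjusted p = 0.0608), and 0.95 when normalised on nuclear coding genes (adjusted p = 0.0207). With all units 5 adhesion genes fell and 3 rose (3 and 1 when adjusted over the list alone), 2 and 1 of plasma cell identity (1 and 1), and CD44, SDC1 and NSD2 did not pass (adjusted p = 0.0913, 0.0541 and 0.297).

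In IM9 without the library of mouse M361, the marrow units had less RNA of the stress and immediate early factors and of CXCR4. They had more beta-globin RNA, whose source, tumour or host, could not be told apart. With all units edgeR called 0 genes (940 at an unadjusted p under 0.05), limma-voom 4 and DESeq2 104. Without the library of mouse M361, which is not an IM9 library and acts through the shared spread, edgeR called 260, 204 lower and 56 higher, and 584 with the block, 255 of them shared. EGR1 had −5.95 ± 0.73 (adjusted p = 0.00187), FOS −5.82 ± 1.00 (adjusted p = 0.00777) and JUN −5.53 ± 0.56 (adjusted p = 0.000244). CXCR4, the receptor for the marrow chemokine CXCL12, went from 13.5 ± 7.96 to 2.82 ± 0.380 CPM (SD, n = 2 each; −2.28 ± 0.39, edgeR adjusted p = 0.00711). ITGA4 rose by 1.39 ± 0.31 (adjusted p = 0.0438). The metallothionein genes MT1X and MT2A, members of a family of similar sequences, had −4.98 ± 0.64 and −4.78 ± 0.80, with a chip level of MT1X of 100 ± 104 CPM that differed widely between both mice.

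HBB in IM9 without that library went from 0.783 ± 0.636 to 65.9 ± 3.83 CPM (log2 fold change 6.33 ± 0.88, adjusted p = 0.00234), and LZTFL1, which regulates ciliary trafficking, rose by 2.71 ± 0.37 (adjusted p = 0.00213). The fatty acid receptor gene CD36 had 2.32 ± 0.51 (adjusted p = 0.0381, and 0.0706 with the block). Of 31 immediate early genes 20 fell, 29 when adjusted over the list alone (median −2.60, adjusted p = 0.0383 with an estimated correlation, and 0.096 with the block as well). Of 27 p53 targets 2 fell, BBC3 at −1.95 ± 0.40 and SESN1 at −1.26 ± 0.29, and 9 when adjusted over the list alone (adjusted p = 0.0383 with an estimated correlation, and 0.096 with the block as well). Of 16 heat shock genes 4 fell, 7 when adjusted over the list alone, with BAG3 at −2.0 ± 0.28 and DNAJB1 at −2.61 ± 0.38 (adjusted p = 0.315 with an estimated correlation).

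Whether the difference between sites itself differed between the lines was tested directly. HMGA1, a chromatin architecture protein gene, and PA2G4, a growth regulator gene, were singled out in the study's own publication, in part from these samples, so their values here are not independent evidence. Across the lines HMGA1 had −0.13 ± 0.66 (adjusted p = 0.927) and PA2G4 −0.28 ± 0.68 (adjusted p = 0.839) with all units, and 0.19 ± 0.20 and 0.03 ± 0.18 without the library of mouse M361. In MM.1S without that library HMGA1 went from 313 ± 37.5 CPM in chip to 481 ± 83.1 in marrow (SD, n = 3 each; 0.60 ± 0.21, edgeR adjusted p = 0.221) and PA2G4 had 0.42 ± 0.18 (adjusted p = 0.361). In IM9 both were above 0 without passing, at 0.35 ± 0.26 and 0.24 ± 0.22. In OPM2 HMGA1 had −0.51 ± 0.24 (adjusted p = 0.0929) and PA2G4 −0.66 ± 0.20 (adjusted p = 0.0145). The line difference passed without that library for HMGA1 (adjusted p = 0.0374), PA2G4 (0.0169) and MYC (0.0289), and with all units it did not (0.647, 0.67 and 0.549). In simulated counts 2% of 8-fold line differences were recovered with all units and 84% without that library, so a missing call with all units says little.

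The line difference passed for 519 genes with all units and 0 with the mouse as a block (edgeR, 4263 at an unadjusted p under 0.05). Without the block 5312 passed by DESeq2 and 1507 by limma-voom. Without the library of mouse M361 it passed for 8260 genes in edgeR, and for 9105 with the block as well. IRF4, higher in MM.1S and lower in OPM2, had a line difference at adjusted p of 0.000639, ITGA4, higher in IM9 and lower in OPM2, at 0.000359, CXCR4 at 0.00125 and TXNIP at 0.000233. These values are without that library. For FOS, EGR1 and JUN no line difference was detected there (adjusted p = 0.515, 0.286 and 0.15), but with the mouse as a block as well JUN passed (adjusted p = 0.013). Genes lower in marrow without that library were shared between lines more often than chance gives: 48 between MM.1S and IM9 against 2.12 expected (one-sided Fisher's exact test, p = 3.17e-51), 112 between MM.1S and OPM2 against 50.5 (p = 4.87e-18) and 101 between OPM2 and IM9 against 36.7 (p = 7.74e-25). With all units, where IM9 had 0 calls in edgeR, MM.1S and OPM2 shared 5 against 0.567 (exact test, p = 8.3e-05). For genes higher in marrow without that library the overlaps by the same exact test were 1 against 0.258 (p = 0.228), 46 against 38.3 (p = 0.0823) and 16 against 17.2 (p = 0.679). Among nuclear coding genes alone, a background chosen after seeing the data, the lower overlaps by the same exact test were 48 against 3.29 (p = 1.48e-42), 111 against 79.1 (p = 2.01e-05) and 100 against 55.8 (p = 1.54e-11). Across 11075 genes, again without that library, the fold changes of these pairs of lines had Pearson's r of 0.216, 0.108 and 0.007 and Spearman's rho of 0.185, 0.088 and −0.046, with the same sign in 56.2%, 53.3% and 46.9%. Genes are not independent replicates in these tests. The calls of the lines also come from 1 fit with a shared estimate of spread for each gene, whereas the expected overlaps assume independent calls. The overlap p-values of the exact tests may therefore overstate the certainty.

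RNA of blood cells was measured as a check on the sorted fractions, which were selected for the tumour cells' fluorescent proteins. Across the lines without the library of mouse M361, 4 of 9 neutrophil genes rose, 5 when adjusted over the list alone (adjusted p = 0.27 with an estimated correlation), among them LTF, the lactoferrin gene, at 5.37 ± 0.89 (adjusted p = 0.00342, and 0.0516 with the block) and MPO, the myeloperoxidase gene, at 5.39 ± 0.90 (adjusted p = 0.00334). Of 12 haemoglobin and erythroid genes HBG2 at 5.38 ± 0.96 and HBB rose and TFRC fell (−1.61 ± 0.32), with 4 higher and 1 lower when adjusted over the list alone (adjusted p = 0.626 with an estimated correlation), and with the block HBG2, HBB and TFRC had adjusted p of 0.0925, 0.232 and 0.108. With all units 1 neutrophil gene and 0 erythroid genes passed in edgeR, 5 higher, and 3 higher and 1 lower, when adjusted over the list alone (adjusted p = 0.115 and 0.672 with an estimated correlation). Globin genes share sequence with their paralogues. In IM9 2 of 9 neutrophil genes rose, 5 when adjusted over the list alone (adjusted p = 0.0383 with an estimated correlation, and 0.173 with the block as well). In OPM2 8 of 9 rose, 8 when adjusted over the list alone (adjusted p = 0.124 with an estimated correlation), and in MM.1S 0 passed in edgeR, 1 when adjusted over the list alone (median 0.47, adjusted p = 0.46 with an estimated correlation). Levels were low: in marrow units MPO reached at most 8.13 CPM, LTF 6.22, HBB 208 and HBG2 52.7, and S100A8, abundant in neutrophils, was at 0 in all.

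The xenograft cells were compared with the same lines in culture, with 1 culture library per line, so that the line was the replicate. FCRL5, a surface receptor of B and plasma cells, was higher in the mouse in every line, at 1.81 CPM in culture and 58.3 in the xenograft for MM.1S, 4.15 and 88.7 for OPM2, and 2.76 and 46.7 for IM9 (log2 fold change 4.5 ± 0.47, adjusted p = 0.0388). It was the only gene of 22016 tested to pass in edgeR, with 1694 at an unadjusted p under 0.05. It was chosen by the naming rule and passed in 11 of the 14 alternatives. FOS had 6.72 ± 0.79 (adjusted p = 0.0577). Of 31 immediate early genes none passed and 15 did when adjusted over the list alone (median 1.97, adjusted p = 0.675 with an estimated correlation). HMGA1 had −0.07 ± 0.45 and PA2G4 −0.37 ± 0.44 (adjusted p = 0.965 and 0.772).

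Without IM9, whose xenograft libraries differed from their culture in mitochondrial rRNA, 292 genes passed, 246 higher and 46 lower in the mouse. From the chip libraries of MM.1S and OPM2 alone 6 passed, all higher, and from their marrow libraries without that of mouse M361 33 passed, 27 higher and 6 lower. This compares 2 lines, each with 1 culture library and 1 xenograft sum, which give little information on the spread. The p-values there rest on a spread borrowed across genes and overstate the certainty. FOS had 7.71 ± 0.66 and passed, from 0.850 to 299 CPM in MM.1S and 3.48 to 441 CPM in OPM2. The xenograft value sums both sites, and in the comparison of sites FOS had 515 and 565 CPM in chip and 4.07 and 5.74 CPM in marrow of these lines. CCR2, the receptor of the chemokine CCL2, also passed, with 21.1 CPM in culture and 281 in the xenograft of MM.1S and 0 and 16.3 in OPM2. The B cell receptor component genes CD79A and CD79B had 3.52 ± 0.55 and 3.23 ± 0.63. SULF1, an enzyme gene that edits heparan sulfate, fell from 133 to 19.7 CPM in MM.1S and from 87.5 to 2.15 in OPM2 (−4.02 ± 0.55), and BMF, a pro-apoptotic gene, had −3.34 ± 0.57. Of 31 immediate early genes 16 rose and 1 fell, 21 and 1 when adjusted over the list alone (median 2.47, adjusted p = 0.899 with an estimated correlation). By site, and without the marrow library of mouse M361, the list's median difference from culture was 3.65, 2.11 and 1.05 in chip and 0.73, 0.48 and −1.69 in marrow for MM.1S, OPM2 and IM9.

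The positions of the genes singled out, on GRCh38 with GENCODE v29, are as follows. FOS (ENSG00000170345) spans chromosome 14 from 75278774 to 75282230, FOSB (ENSG00000125740) chromosome 19 from 45467995 to 45475179, and JUN (ENSG00000177606) chromosome 1 from 58780788 to 58784327. CDKN1A (ENSG00000124762) spans chromosome 6 from 36676460 to 36687339, and HBB (ENSG00000244734) chromosome 11 from 5225464 to 5229395. CTAG2 (ENSG00000126890) spans chromosome X from 154651972 to 154653579, and TXNIP (ENSG00000265972) chromosome 1 from 145992435 to 145996600. PCSK5 (ENSG00000099139) spans chromosome 9 from 75890644 to 76362339, LZTFL1 (ENSG00000163818) chromosome 3 from 45823316 to 45916042, and FCRL5 (ENSG00000143297) chromosome 1 from 157513377 to 157552520. All are protein-coding, and values are sums over their annotated transcripts.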

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

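The tests of explanations here were all chosen after the results they weigh had been seen, while the line difference and the search for outlying libraries were planned.

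HBB in the right-side IM9 chip library of mouse M964 had a log2 CPM of 1.13, against −1.63 to −1.29 in the other IM9 chip libraries. The gap was 0.879 of the group's range, above Dixon's 95% critical value. It was the 1 library picked out in 52 such tests, which is no more than chance gives. An unmatched transcript with the length of the large ribosomal RNA took 20.25% of the counts in the left-side IM9 marrow library of mouse M962, against 0.0111% to 1.42% in the cultures. Another with the length of the small ribosomal RNA took 10.58% in the right-side IM9 chip library of mouse M962, against 0.0164% to 0.133% in the cultures. Neither enters any comparison.

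The difference between marrow and chip itself differed between lines for 519 genes with all units and for 8260 without the OPM2 marrow unit of mouse M361. Among the genes named with all units, the adjusted p of the line difference was 0.0493 for FOSB, 0.0493 for the antisense gene IL10RB-DT, 0.0461 for PCSK5, 0.0493 for ACTL8 and 0.0493 for CKAP2L. FOSB was lower in every line and by more in MM.1S, whereas PCSK5 stood out in OPM2. With the mouse as a block and all units, 0 genes had a line difference in edgeR (4263 at an unadjusted p under 0.05), so none of these calls held there. With the block and without the OPM2 marrow unit of mouse M361, 9105 genes had one. The loss with all units therefore cannot be laid to the pairing alone.

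In the broad difference in OPM2, a single poor library, that of mouse M361, is argued against as the whole cause, since 13175 genes were called without it. With all units 4216 were called among nuclear coding genes alone, but this total says little on scaling by mitochondrial and non-coding RNA. A shift of scale can turn lower calls into higher ones and leave the total alike. It moved the directions of these genes from 2561 higher and 1713 lower to 3517 and 699, so it may account for part of the lower calls. Normalised on nuclear coding genes without that library, 4287 rose and 3718 fell. A single shift of scale cannot give calls in both directions, so scaling is argued against as the whole cause there. A different makeup of the RNA in the OPM2 marrow libraries stays open and may account for much of it: genes outside the nuclear coding set had a median log2 fold change 1.74 above that of nuclear coding genes in OPM2, against 0.05 in MM.1S and −0.01 in IM9. The real split was the 1 of 10 splits of the 6 OPM2 units with as many genes (7738, highest other 2), and 10 splits are too few to judge chance. Whether growth in the marrow changed OPM2 cells was not tested apart from these.

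Blood cell transcripts, mainly HBB, HBG2, LTF and MPO, were higher in marrow across lines without the library of mouse M361. With all units these named genes did not pass in edgeR (adjusted p from 0.053 to 0.308), whereas the neutrophil collagenase gene MMP8, at very low levels, did. Without that library, HBB, HBG2 and LTF lost the call with the mouse as a block (0.232, 0.0925 and 0.0516). Human neutrophils left in the sorted cells are argued against, since S100A8 and S100A9, abundant in them, reached at most 0.681 CPM in a marrow unit, with S100A8 and ELANE at 0, CAMP at most 0.268, MPO at most 8.13 and LTF at most 6.22. RNA of the mouse host read through conserved sequence could still be the source and cannot be told apart from expression by the tumour cells: over the 16 erythroid and neutrophil genes under 1 CPM in culture, the lowest line median of marrow minus chip was 0.17 in IM9, with 0.32 in MM.1S and 3.35 in OPM2, and 9, 9 and 14 of the 16 were higher. The sort selected for tumour fluorescence, but no measure of its purity was used here, so host cells carried over and free host RNA both stay possible. No mouse sequence was used here to separate the reads. The rule for this test was made stricter, by asking for more members on one side than chance gives, after its first outcome had been seen.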

How the results depend on the processing

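The fits without the OPM2 marrow unit of mouse M361 (as more than a left-out unit), on nuclear coding genes only, on MM.1S and IM9, on IM9 alone with sides apart, on OPM2 alone without that unit, with the block without it, and on culture of MM.1S and OPM2 by site were chosen after seeing the data. All 11 genes named across lines kept their direction in 28 alternatives, with 230 of 308 values past the threshold, as did the 3 named in MM.1S (65 of 81), the 16 in OPM2 (410 of 434) and FCRL5 (11 of 14). Counts moved by more than 1.5 times as follows, and the cause was not tested unless stated. Across lines (19) they were 502 with no filter, 4 with the replicate block, 86 with IM9 sides kept apart, 913 by DESeq2, 572 for MM.1S and IM9, and without mouse M361's marrow 88 with the block, 552 with block and sides apart and 470 for nuclear coding genes. In MM.1S (11) they were 93 with no filter, 7 with length-scaled TPM, 0 with the block, 27 with sides apart, 22 by limma-voom, 182 by DESeq2, 2777 with that line alone, and without that unit 858 with the block and 367 for nuclear coding genes. In OPM2 (7738) they were 3534 with the block, 4216 for nuclear coding genes, fewer of which are tested, 0 with that line alone (edgeR, 4263 at an unadjusted p under 0.05, 10264 by DESeq2 and 9939 by limma-voom in all lines) and 13221 with the block without that unit. In IM9 (0) they were 62 with no filter, 137 with sides apart, 4 by limma-voom, 104 by DESeq2, 8 with that line alone, 980 alone with sides apart and 2226 with the block too, and without that unit 584 with the block and 306 for nuclear coding genes. For the line difference (519) they were 885 with DESeq2 size factors, 2574 with no filter, 309 with length-scaled TPM, 0 with the block, 5233 with sides apart, 1443 for nuclear coding genes, 1507 by limma-voom, 5312 by DESeq2, and without that unit 9105 with the block and 5837 for nuclear coding genes. For culture (1) they were 10 with DESeq2 size factors, 179 with no filter, 0 with length-scaled TPM, 0 for nuclear coding genes (786 at an unadjusted p under 0.05), 15 by limma-voom, 243 by DESeq2, 10 in an additive fit of all units, 7 from chip libraries, and for MM.1S and OPM2 6 from chip and 33 from marrow. The 25 lists were 1 with an estimated correlation, 5 by fry and 13 for nuclear coding genes.

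Leaving out each unit in turn gave 7 to 517 genes across lines, 0 to 406 in MM.1S, 4826 to 13175 in OPM2, 0 to 260 in IM9, 0 to 8260 for the line difference and 17 to 26 lists, and leaving out a line gave 61 (OPM2), 116 (MM.1S) or 292 (IM9) genes for culture. The highest count of genes was each time the fit without OPM2 marrow M361, and leaving out any MM.1S marrow unit left 0 genes in MM.1S. A lone IM9 unit left in a group was assumed to vary like the other groups. KDM3A across lines turned to −1.02 without OPM2 marrow M361, −0.756 for MM.1S and IM9, −0.926 with block and sides apart and −0.931 for nuclear coding genes without that unit. TOP2A in OPM2 was 0.662 with length-scaled TPM. In OPM2 without that unit, then alone, with the block and for nuclear coding genes, JUN was −4.57, −4.74, −4.98 and −4.36, TP53I3 −0.226, −0.378, −0.474 and −0.0136, NUSAP1 −1.93, −2.05, −2.0 and −1.71, KIF20A −2.06, −2.18, −2.16 and −1.84, DNAJB1 −4.46, −4.60, −3.95 and −4.26, and HSPA1B −4.31, −4.47, −3.55 and −4.12. CXCR4 and CCND2 there were 0.952 and 0.613 for nuclear coding genes without that unit, and 0.74 and 0.391, uncalled, without that unit alone. Leaving out each unit in turn ranged up to 2.84 for JUN, 8.68 for TP53I3, 2.82 for NUSAP1, 0.692 for KIF20A, 3.2 for DNAJB1 and 2.6 for HSPA1B, and without M361's marrow alone each was below 0. For these genes, which turned when that unit alone was left out, the cause is that unit, and for TOP2A it was not tested. Beside the values given here and beside each result, the block changed no other call between sites, of a gene or a list, that the text leads with. Scaling on nuclear coding genes gave a median shift in log2 fold change of 0.221 across lines and 0.585 in OPM2, over 15841 genes. For culture it gave 0.142 over 14232 genes. DESeq2 size factors and length-scaled TPM gave median shifts of −0.204 and −0.101 for culture, over 22016 and 21929 genes. In IM9 24% of simulated 16-fold changes were recovered with all units and 94% without that unit, at unchanged depth. The simulation drew every unit with the spread estimated from the units kept, so the simulated IM9 counts were themselves noisier with all units. It therefore cannot show how far the shared estimate alone sets that limit in the real data. What depth limits was not tested.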

Other observations

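The tests of handling, depth and site and the readings of other splits in this part were chosen after the results had been seen, as was the use of the fit without the marrow library of mouse M361, whereas the gene lists were planned.

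Further gene groups moved in OPM2 marrow without the library of mouse M361, which carried the raised mitochondrial share already given. Of 29 lysosome and autophagy genes 22 fell and 3 rose, 23 and 3 when adjusted over the list alone (median −1.36, adjusted p = 0.0529 with an estimated correlation). The protease gene CTSB had −2.71 ± 0.27 and ATP6AP1, an accessory subunit of the proton pump, −2.42 ± 0.23. Of 30 proteasome genes 21 fell and 1 rose, 22 and 1 when adjusted over the list alone, with PSMD2 at −2.35 ± 0.22 (adjusted p = 0.211 with an estimated correlation). Of 35 actin and motility genes 23 fell and 1 rose, 25 and 1 when adjusted over the list alone, among them ZYX, a focal adhesion gene, at −2.83 ± 0.34, RAC2 at −2.25 ± 0.27 and MSN at −1.98 ± 0.21 (adjusted p = 0.124 with an estimated correlation). Of 17 genes of MHC class I presentation 10 fell, 10 when adjusted over the list alone, with the peptide transporter gene TAP1 at −2.76 ± 0.31 and TAPBP at −2.12 ± 0.23 (adjusted p = 0.131 with an estimated correlation). Against these, 27 of 65 cytosolic ribosomal protein genes rose and 7 fell, 27 and 8 when adjusted over the list alone, with RPL9 at 1.75 ± 0.20 and RPLP2 at 1.81 ± 0.22 (adjusted p = 0.9 with an estimated correlation); these short genes have many pseudogenes.

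In MM.1S without that library, 5 of 33 matrix and mesenchymal genes fell, 8 lower and 1 higher when adjusted over the list alone, among them THBS1, an adhesive glycoprotein gene, at −3.33 ± 0.48, LGALS1 at −1.20 ± 0.25 and TGFB1 at −1.16 ± 0.25 (adjusted p = 0.125 with an estimated correlation). The granulysin gene GNLY, of the T and NK cell list, went from 7.30 ± 2.37 CPM in chip to 33.7 ± 14.8 in marrow (SD, n = 3 each) and was the 1 of 15 members to pass, 3 when adjusted over the list alone (adjusted p = 0.131 with an estimated correlation). In IM9, 5 of 24 unfolded protein response genes fell, 5 when adjusted over the list alone, with the chaperone gene DNAJB9 at −2.64 ± 0.35 and HERPUD1 at −2.08 ± 0.32 (adjusted p = 0.535 with an estimated correlation, and 0.0722 with the block at the preset one). In the joint fit of the 3 lines against culture, 0 of 27 cholesterol synthesis genes had a positive log2 fold change (median −0.84) and 1 of 24 amino acid response genes did (median −1.13). These joint values do not give the direction in each line. All 15 replication-dependent histone genes tested were above 0 (median 2.59, 7 when adjusted over the list alone), and the interferon genes OAS3 and MX1 had 3.24 ± 0.54 and 2.69 ± 0.50 without passing (7 of 39 interferon genes when adjusted over the list alone). None of these culture lists had a member past the threshold over all genes in edgeR, where 1694 genes had an unadjusted p under 0.05, or held with an estimated correlation (adjusted p = 0.675 or 0.68). All these culture values include IM9, whose xenograft and culture libraries differ widely in mitochondrial rRNA. How far such a difference in RNA makeup moved these lists, the histone genes included, was not tested.

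The immediate early list lay lower in marrow in every line. Chance is argued against by other splits of the units within lines, which ignore the pairing by mouse. The real split alone gave as many genes without the library of mouse M361 (1 of 60 splits, 517 genes, highest other 0). Lower depth of marrow libraries is argued against by MM.1S, where depths were alike and the list's median was −2.89. Mincing and digestion of the chip tumours is a candidate explanation in MM.1S and OPM2, whose marrow cells lay within 0.73 of culture at the list's median while the chip cells lay 3.65 and 2.11 above it. In IM9 the marrow cells lay at −1.69 and the chip cells at 1.05, which leaves handling open there, since culture and xenograft libraries differ in mitochondrial rRNA (0.900% against 35.3% to 42.0%); this line was given its own test after a joint test had spoken against handling. Site of growth and handling cannot be told apart, because the number of sites at which both handlings were used is 0.

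Other splits were counted for the remaining results. For the 19 genes across lines 1 of 60 splits gave as many (highest other 0), so chance is argued against by splits that ignore the pairing by mouse. With site swapped within mice in the blocked fit, the real one alone gave as many as 4 genes (1 of 30, highest other 2). Without the library of mouse M361 it alone gave as many as 88 genes (1 of 30, highest other 1). A share of 1 in 30 is the smallest that 30 swaps can give, so chance is argued against there but not excluded. The real split gave 25 lists and 2 of 60 splits gave as many, the real one included, but another split gave more (26). Without the library of mouse M361 it gave 18 and 19 of 60 splits gave as many (highest other 24), so chance is not excluded for the number of lists. With an estimated correlation the highest number of lists in any other split was 0, and the largest absolute median of the immediate early list in another split was 1.365 with all units and 1.51 without that library, against −2.42 and −2.21. Within MM.1S the real split was the 1 of 10 with 11 genes (highest other 0), and the 1 of 10 with 406 without that library (highest other 1). Against culture it was the 1 of 4 with 1 gene (highest other 0). Splits of 10 and of 4 are too few to judge chance.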
